A study of Mus musculus with 12 samples.

How the data were processed

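Total RNA of whole gastrocnemius muscle of CD1 mice, adult and male per the labels, was labelled with Cy3 and hybridised to 12 one-colour Agilent mouse arrays, 3 per group. The groups were WT control, WT denervated, KO control and KO denervated, with 14 days of denervation. Groups and replicate numbers were taken from the sample titles.

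The deposited scanner files hold intensity per spot. Per the file headers the processed signal is intensity after background subtraction with spatial and multiplicative detrending, with surrogate values for dim spots and no normalization between arrays. The headers name Feature Extraction 10.7.3.1, whereas the processing notes of the samples name 10.5.1.1. The deposited series matrix, the table of processed values, holds intensity on a linear scale that appears quantile-normalized between arrays, since its quartiles are nearly equal on every array. The authors' method is not stated there. The slide and the scan day were read from the headers. Slide 1 held WT denervated replicate 1, WT control replicate 1 and KO denervated replicate 1. Slide 2 held WT control replicate 2 and KO control replicate 2. Slide 3 held WT control replicate 3, KO denervated replicate 3 and KO control replicate 3. Slide 4, scanned on the other day, held WT denervated replicates 2 and 3, KO control replicate 1 and KO denervated replicate 2.

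Each array held 43379 spots other than controls, for 41174 probes. Control spots were left out, spots marked as outliers by the scanner software were set missing, and spots of a probe were averaged. The signal was log2-transformed and the 75th percentile of the array subtracted. The lowest signal that counted as well above background was between 10.7 and 16.5 intensity units by array. Probes were named through a RefSeq table: 24375 by accession, 6301 by symbol and 2426 by synonym, while 8072 kept the name in the file. This gave 27597 genes or names. A probe was kept when well above background, as the scanner software marks it, on all 3 arrays of at least 1 group. Of the 22524 probes kept, the one with the highest mean signal stood for its gene, which left 15226 genes. Of these, 226 had a missing value on an array. Probe positions are on mouse build mm8, as in the files, and no mm8 genome was used here.

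Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on all 12 arrays with 4 group means and no covariate. There were 6 comparisons: denervation in each genotype, KO against WT in each condition, the interaction of denervation and genotype, and KO against WT averaged over conditions. P-values were adjusted by Benjamini and Hochberg within each comparison, and genes with an adjusted p under 0.05 were called. Residual degrees of freedom were 8 and prior degrees of freedom 3.16. An exact permutation test of 3 against 3 arrays cannot give a p under 0.1, so single genes were tested only in limma's fit across all genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the figures. The fit was tested on simulated data of 15000 genes. For KO against WT in denervated muscle it called 2%, 34%, 96% and 96% of genes shifted by 0.5, 1, 2 and 3 on the log2 scale, with 3 unshifted genes among the calls (2.56%). For the interaction it called 2%, 16%, 80% and 88%, with 5 unshifted genes (5.10%). There were 50 shifted genes per size. The simulated noise was independent between genes and between arrays, with no effect of slide, pairing or denervation. These shares therefore need not hold for the real arrays.

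The comparisons, the test, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The rule names Smad4 and 17 genes of a fixed panel in every comparison. It adds the 8 largest rises and the 8 largest falls among called genes that were well above background on all arrays of the groups compared, that had a gene symbol, and whose groups of arrays did not overlap. For the interaction, where arrays do not part into 2 groups, the last condition was not applied, and for the average it was required in both conditions. Up to 3 genes per comparison are given as bounds: these are called genes of which no probe was well above background on any array of the dimmer group. Each array of that group was set at its lowest signal well above background, unless the gene's own signal was higher. That limit is the lowest over all probes, and a single probe may need more signal to be told from background. The bounds are therefore approximate. From each list described, up to 4 members with the smallest adjusted p could be named. Some genes that the rule names are not reported here. Where a gene named in 1 comparison is given in another, its value there is quoted whatever its size.

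The 33 lists held 689 members, of which 640 were measured. Of the members, Trim72, Myh7b, Kcna7, Irs2, Ly6g, Pck1, Hbb-b2 and Flg were not on the array. Of the lists, 11 hold markers of cell types that whole muscle may contain, and muscle fibres express some of these too. Lists were tested with camera, which asks whether the members differ from all other genes, with a preset correlation of 0.01 between genes and adjustment over the lists of a comparison. They were also tested with camera using a correlation estimated for each list, and with fry.

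The alternatives were normexp background correction of the mean signal with an offset of 50, quantile normalization, scaling by the array median, no filter, a filter on all 12 arrays, and the mean of all probes of a gene. Further ones were slide as a fixed or a random block, values within slides, the replicate number as a block, the values of the series matrix, array weights, eBayes with trend and robust, only the arrays of the 2 groups compared, and leaving out each array. For denervation and the interaction the replicate block was the number within a genotype, in KO as well as in WT. For KO against WT it was the number across genotypes, which ties different animals. A form of the normexp correction without spots whose local background exceeded 3 times the array median was added after the data were seen. It set these spots and those marked as outliers missing before the correction, whereas the planned form set outliers missing after it. A random block of the WT arrays with the same number, each KO array being a block of its own, was also added after the data were seen. The random slide block had a correlation of 0.122. After group means were removed, WT arrays of the same number correlated across genes, which are not independent replicates. Their r was 0.304, 0.107 and 0.232, against at most 0.016 for other numbers. In KO muscle r was 0.0899, 0.0152 and 0.175 for numbers 1, 2 and 3, and the arrays of number 3 shared a slide. Between genotypes r was under 0.1 for at least 1 number. Between WT and KO denervated arrays, which are of different animals, r was 0.203 and 0.299 for numbers 1 and 2. Between control arrays it was 0.163 for number 2 and -0.098 for number 3. All of these pairs of a WT and a KO array shared a slide, as did the WT arrays of number 1. An r of this size therefore does not by itself show that arrays came from the same animal. The WT arrays of numbers 2 and 3 did not share a slide. The random block of the WT pairs had a correlation of 0.0805. Sequence data and protein data were not used here.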

Results

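Gene expression was measured in the gastrocnemius, a calf muscle, of adult wild-type and Smad4 knockout CD1 mice. Smad4 is the Smad protein that receptor-activated Smads of both the TGF-beta and the BMP pathway bind. One array was hybridised with RNA of each of 12 muscles. These fell into 4 groups of 3: control and 14-day denervated muscle of wild-type (WT) mice, and control and 14-day denervated muscle of Smad4 knockout (KO) mice. Per the labels, the 3 experiments of each condition were independent and used different animals. Within a group the p-values below therefore rest on the spread between animals, as far as the labels allow. WT arrays of the same number correlated, however, and it is not known whether control and denervated muscle of a number came from the same animal. The main fit has no block for this. Each array carried 41174 probes, of which 50.1% to 56.4% were well above background. The 75th percentile of the signal lay between 226 and 383 intensity units, and no spot was saturated. The number of arrays limits the precision of every value below. After scaling, arrays of the same group correlated across genes with r between 0.974 and 0.985 (genes are not independent replicates). The first principal component held 66.1% of the variance and parted all 6 denervated arrays from all 6 control arrays. The arrays lay on 4 slides that were scanned on 2 days, and no slide held all 4 groups.

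Smad4 was lower on every KO array than on any WT array of the same condition. It is represented by 2 probes, A_51_P444740 at 73764362 to 73764396 and A_52_P611867 at 73764420 to 73764479 on the minus strand of chromosome 18 (mm8), and both were well above background on all 12 arrays. On the scale used here, log2 signal minus the array's 75th percentile, the brighter probe A_52_P611867 averaged 3.79 ± 0.22 (SD, n = 3) in WT control, 3.32 ± 0.16 in WT denervated, 2.33 ± 0.12 in KO control and 1.90 ± 0.14 in KO denervated muscle. The means of A_51_P444740 were 1.88 ± 0.11, 1.46 ± 0.14, 0.47 ± 0.12 and -0.10 ± 0.31 in the same order. Averaged over conditions, Smad4 was 2.71-fold lower in the KO (log2 -1.44 ± 0.11 SE, limma adjusted p = 4.04e-04). The labels do not say which part of the gene was deleted, and the probes may lie outside it, so it is unknown whether these values check the deletion. Signal remained in KO muscle, and whole muscle also holds cells other than fibres. Which cells had lost the gene is not stated in the labels.

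**Figure D1:**
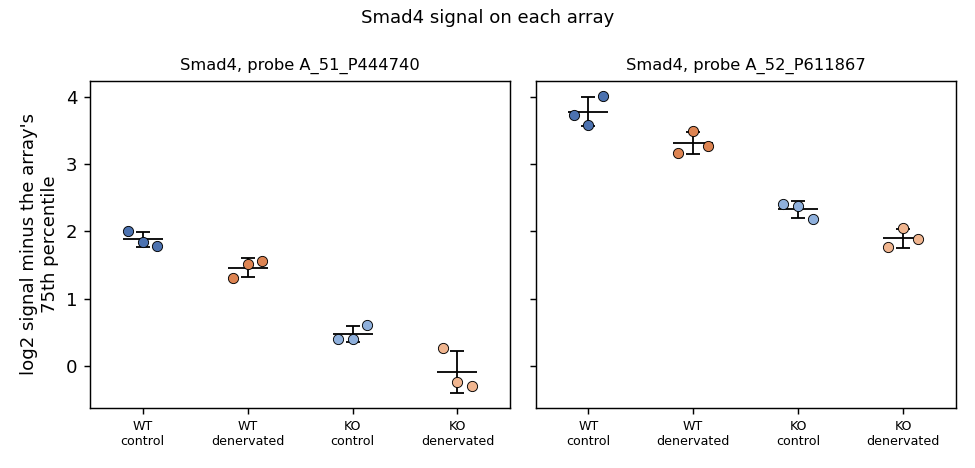
Signal of the 2 Smad4 probes on each of the 12 arrays (log2 signal minus the array's 75th percentile; points, arrays; horizontal bar, mean; error bar, SD of 3 arrays). On probe A_52_P611867 the KO arrays lie between 1.77 and 2.42 and the WT arrays between 3.18 and 4.02.

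The comparison of denervated with control WT muscle asks what 14 days without nerve did to gene expression when Smad4 was present. Several genes of the acetylcholine receptor and of embryonic muscle rose. Chrna1, which encodes the alpha subunit of the receptor, rose by 4.51 ± 0.13 (log2, SE, n = 3 against 3; adjusted p = 8.03e-09), Chrnd, the delta subunit, by 5.96 ± 0.16, and Musk, the receptor kinase that organises the neuromuscular junction, by 3.24 ± 0.29. Chrnd and Musk were well above background on only 2 of the 3 WT control arrays, so their sizes are less certain. Chrng, the subunit of the fetal receptor, rose from a level not well above background on the WT control arrays, and the smaller change of its 2 probes was 4.21. The myogenic factor Myog rose by 4.50 ± 0.37, embryonic myosin heavy chain Myh3 by 4.80 ± 0.58, the neural cell adhesion molecule Ncam1 by 4.25 ± 0.44, although 1 of its 8 probes had the other sign, and the deacetylase Hdac4 by 2.92 ± 0.14. The transcription factor Runx1 also rose from such a level, and the smaller change of its 2 probes was 1.55. Among the 8 largest rises of genes well above background in both groups were those of keratin Krt18 (9.69 ± 0.85), the sarcomeric protein Igfn1 (6.89 ± 0.55), the small GTPase Rrad (6.53 ± 0.41), the adhesion molecule Nrcam (6.38 ± 0.39), the cardiac ankyrin repeat protein Ankrd1 (6.19 ± 0.31), the BMP family ligand Gdf5 (5.96 ± 0.34) and Plekhh1 (5.86 ± 0.25). Among genes seen on no WT control array, Bpifb1 was at least 66.5-fold higher, Gsta1 at least 65.1-fold and Clca1 at least 37.1-fold.

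The largest falls after denervation of WT muscle were those of Dhrs7c, a dehydrogenase of the sarcoplasmic reticulum (-5.21 ± 0.31, log2 and SE), the muscle-secreted peptide gene Ostn (-4.94 ± 0.36), the phospholipase Pla2g5 (-4.27 ± 0.45), the receptor subunit Ramp1 (-4.23 ± 0.37), the lactate transporter Slc16a3 (-4.01 ± 0.24), the mitochondrial regulator Perm1 (-3.86 ± 0.41), the water channel Aqp4 (-3.86 ± 0.51) and Fbp2, the fructose bisphosphatase of muscle (-3.85 ± 0.20). Myostatin (Mstn), an inhibitor of muscle growth, fell by 2.25 ± 0.18, and the corepressor Dach2 was at least 3.13-fold lower. The ubiquitin ligase genes Fbxo32 and Trim63, widely used as markers of muscle atrophy, did not pass the test (0.41 ± 0.51, adjusted p = 0.552, and 0.05 ± 0.23, adjusted p = 0.874). The BMP antagonist Nog (0.07, adjusted p = 0.921) and the BMP target Id1 (0.75, adjusted p = 0.156) did not either. Fbxo30, another ubiquitin ligase of muscle, rose by 0.84 ± 0.24 (adjusted p = 0.016). That call ended without WT denervated replicate 2 (adjusted p = 0.0632) or WT control replicate 2, and with slide as a block (adjusted p = 0.139). Fbxo31 fell by 0.94 ± 0.22, but its other probe went the other way (0.37). In all, 5979 of 15226 genes passed the test, 2847 higher and 3132 lower (limma, adjusted p under 0.05), 2760 of them by at least 2-fold. For every gene given with a rise or a fall in these paragraphs on WT muscle, the 3 arrays of one group lay above the 3 of the other, which the rule behind the largest changes requires. In the fit with slide as a fixed block 4494 genes passed, and with the planned normexp correction 1909, 724 higher and 1185 lower.

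Of the 33 gene lists fixed before the data were examined, 14 passed camera, limma's test of a list against all other genes, in WT muscle. Embryonic and denervation-induced genes were the highest as a group: 12 of 17 measured members rose and 2 fell, with a median of 3.90 (adjusted p = 4.89e-07, or adjusted p = 0.176 with an estimated correlation). Gadd45a (3.92), Ankrd1 and the cardiac troponin Tnnt2 (4.34) were among them. Neuromuscular junction genes followed, with 10 of 19 higher and 2 lower (median 0.93, adjusted p = 0.00304, or adjusted p = 0.259 with an estimated correlation). Of 33 proteasome genes 23 rose and none fell over all genes tested, led by Psmb5 (0.97) and Psmd4 (0.88), and adjusted over the list alone 25 rose and 1 fell (median 0.60, adjusted p = 7.08e-07, or adjusted p = 0.509 with an estimated correlation). Energy metabolism went the other way. In glycolysis 16 of 20 genes fell (median -1.14, adjusted p = 6.81e-08, or 0.176 as the adjusted p with an estimated correlation), among them Gpd1 (-2.82) and Tpi1 (-1.77). In oxidative phosphorylation 38 of 53 fell (median -0.66, adjusted p = 1.52e-10, or adjusted p = 0.509 with an estimated correlation), with Sdha at -1.46 and Sdhb at -1.43. In the citric acid cycle and fatty acid oxidation 31 of 37 fell (median -0.83, adjusted p = 7.43e-10, or adjusted p = 0.176 with an estimated correlation), with Ppara at -2.39 and Idh2 at -2.47. Excitation-contraction genes were lower, 9 of 20 falling and 1 rising (median -0.48, adjusted p = 0.0228, or adjusted p = 0.509 with an estimated correlation). Under quantile normalization the adjusted p of this list was 0.0624. Jph2, which ties the sarcoplasmic reticulum to the T-tubule, fell by 1.85, and Cacng1, the gamma subunit of the muscle calcium channel, rose by 1.17.

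Markers of other cell types shifted beside these groups. Endothelial genes were lower (10 of 13 fell, median -0.93, adjusted p = 2.82e-04, or adjusted p = 0.445 with an estimated correlation), as were those of Schwann cells (8 of 13 fell and 1 rose, median -1.28, adjusted p = 0.00227, or 0.559 with an estimated correlation). Ngfr, a neurotrophin receptor, rose by 2.34 on 1 of its 2 probes and was at -0.62 on the other. Smooth muscle and pericyte genes (6 of 10 fell, adjusted p = 0.0272, or 0.545 with an estimated correlation) lost their call without WT denervated replicate 1 (adjusted p = 0.0732). Erythrocyte genes (5 of 6 fell, median -1.35, adjusted p = 0.0324, or 0.559 with an estimated correlation) lost theirs without any 1 of WT denervated replicates 1 and 3 and WT control replicates 2 and 3 (adjusted p up to 0.0841). Macrophage genes were higher (4 of 17 rose over all genes tested and 2 adjusted over the list alone; median 0.43, adjusted p = 0.0286, or 0.66 with an estimated correlation), with Cd68 at 2.00 and Lgmn at 1.12. That call was lost with slide as a block (adjusted p = 0.188) and without WT control replicate 1 or WT denervated replicate 3 (adjusted p up to 0.0808). The last called lists were TGF-beta target genes (8 of 18 rose and 2 fell, adjusted p = 0.0324, or 0.559 with an estimated correlation; Cdkn1a 5.05 and Timp1 3.92) and ribosomal protein genes (4 of 46 rose over all genes tested and 1 adjusted over the list alone; adjusted p = 0.0286, or 0.855 with an estimated correlation). With slide as a block the adjusted p of both was 0.123. Without WT control replicate 3 that of the TGF-beta targets was 0.0531. Without WT control replicates 1 or 2 or WT denervated replicates 2 or 3 that of the ribosomal list reached 0.231.

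The other 19 lists did not pass camera in WT muscle, though members of most did pass the test for single genes. Myogenic regulators (7 of 17 rose and 4 fell, adjusted p = 0.295), ubiquitin ligases (6 and 4 of 21, 0.568), autophagy and lysosome genes (9 and 4 of 33, 0.241) and IGF, Akt and FoxO genes (9 and 6 of 24, 0.337) moved both ways. So did ligands, receptors and antagonists of the TGF-beta and BMP family (10 and 12 of 37, 0.917), whose median was -0.11 and mean 0.25. The BMP ligand Gdf6 was at least 17-fold higher and the activin receptor Acvr2b fell by 2.38. The Smad family (3 and 3 of 12, 0.992; median -0.13, mean 0.05) and BMP target genes (4 and 6 of 14, 0.922) did the same, Id2 rising by 3.63 and Atoh8 by 2.11 while Hey1 fell by 1.08. The adjusted p was 0.541 for extracellular matrix (7 of 32 rose, 3 fell), 0.403 for stress and growth arrest (8 and 7 of 20), 0.917 for polyamine metabolism (3 and 3 of 10, median 0.14 but mean -0.25), 0.917 for the cell cycle (2 and 1 of 17) and 0.337 for satellite cells (4 of 12 rose). For fast-fibre sarcomere genes 4 of 15 fell (0.127), with a median of -0.18 that turned to 0.08 under quantile normalization. It was 0.917 for slow-fibre genes (1 of 13 fell; median 0.03, mean -0.13), 0.568 for fibroblasts (2 of 13 fell), 0.236 for T and B cells (3 of 7 fell), 0.0652 for granulocytes and mast cells (3 of 11 fell), 0.917 for adipocytes (0 of 7; median 0.04, mean -0.09) and 0.943 for skin and hair (1 rose and 1 fell of 3; median -0.43, mean 0.60).

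In KO muscle the same comparison asks what denervation did in the Smad4 knockout. Several of the genes that rose in WT rose again: Chrna1 by 4.36 ± 0.13 (log2, SE, n = 3 against 3, adjusted p = 1.6e-08), Myh3 by 4.54 ± 0.58, Myog by 3.85 ± 0.37, Ncam1 by 2.88 ± 0.44, Hdac4 by 2.75 ± 0.14 and Musk by 1.94 ± 0.29. Musk was well above background on only 2 KO control arrays, so its size is less certain. Chrnd, not well above background on any KO control array, was at least 37.4-fold higher. Among the 8 largest rises of genes well above background in both groups were those of Krt18 (7.39 ± 0.85), the collagen gene Col19a1 (6.84 ± 0.34), agmatinase (Agmat, 6.06 ± 0.43), Plekhh1 (5.82 ± 0.25), Rrad (5.80 ± 0.41), embigin (Emb, 5.74 ± 0.19) and Gdf5 (5.74 ± 0.34). The aldehyde dehydrogenase Aldh3a1 was at least 133-fold higher and Igfn1 at least 94.9-fold. The largest falls were those of the potassium channel Kcnc1 (-5.08 ± 0.31), Dhrs7c (-5.04 ± 0.31), Perm1 (-4.93 ± 0.41), Ostn (-4.75 ± 0.36), Slc16a3 (-4.62 ± 0.24), Tlcd3b (-4.12 ± 0.25), Pla2g5 (-3.90 ± 0.45) and Bdh1, an enzyme of ketone body metabolism (-3.88 ± 0.53). Mstn fell by 2.91 ± 0.18, while Fbxo30 rose by 1.15 ± 0.24. Fbxo31 fell by 1.27 ± 0.22 on the brighter of its 2 probes, of which the other had gone the other way in WT muscle. Dach2 also passed as lower, but it was well above background on only 2 KO control arrays and no KO denervated array, so no size is given. Fbxo32 (0.18, adjusted p = 0.79), Trim63 (0.09, 0.778), Id1 (-0.49, 0.328) and Nog (-0.24, 0.718) did not pass the test. Of 15226 genes 7144 passed, 3608 higher and 3536 lower, 3556 of them by at least 2-fold. For each gene given with a rise or a fall here the 3 arrays of one group lay above the 3 of the other. With slide as a block 6637 genes passed, with the planned normexp correction 2721, 1177 higher and 1544 lower, and without a filter 10053, 3461 higher and 6592 lower. The split of called genes into higher and lower moved with the scaling: 50.5% were higher with the 75th percentile, 54.2% under quantile normalization and 44.5% with the array median.

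Smad4 itself passed the test for denervation in both genotypes, at -0.47 ± 0.15 in WT (adjusted p = 0.0329) and -0.43 ± 0.15 in KO (adjusted p = 0.0415). Neither call was stable. In WT it ended without any 1 of WT denervated replicates 1 and 3 and WT control replicates 1 and 3 (adjusted p up to 0.123). In KO it ended without KO denervated replicates 1 or 3, KO control replicates 1 or 2, WT control replicate 1 or WT denervated replicate 3 (up to 0.121) and with slide as a block (adjusted p = 0.0686).

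Camera called 14 lists in KO muscle, and none kept its call with an estimated correlation. Glycolysis fell in 17 of 20 genes (median -1.60, adjusted p = 7.01e-09, or adjusted p = 0.123 with an estimated correlation), oxidative phosphorylation in 50 of 53 (median -0.98, 1.48e-15, or 0.354), and the citric acid cycle and fatty acid oxidation in 33 of 37 (median -1.25, 2.35e-13, or 0.123). Idh2 at -3.66, Fabp3 at -2.34 and Cox7a1 at -2.03 were among the members. Fast-fibre sarcomere genes fell in 11 of 15 (median -0.82, but -0.20 under quantile normalization; adjusted p = 2.32e-04, or 0.411 with an estimated correlation), with an adjusted p of 0.413 under that normalization and the calcium-binding Casq1 at -2.39, and excitation-contraction genes in 13 of 20 (adjusted p = 3.03e-04, or 0.354). Embryonic and denervation-induced genes rose in 11 of 17 (median 3.62, or 2.88 with dim genes at their bound; adjusted p = 2.32e-04, or 0.354) and proteasome genes in 21 of 33 (adjusted p = 1.63e-04, or 0.561). Neuromuscular junction genes rose in 10 of 19 (adjusted p = 0.0312, or 0.411), a call lost with slide as a block (adjusted p = 0.0664). TGF-beta target genes rose in 8 of 18 (adjusted p = 0.0213, or 0.561), and without KO denervated replicate 1 or KO control replicate 2 their adjusted p reached 0.0545. Beside these, macrophage genes rose in 9 of 17 (adjusted p = 0.00156, or 0.579), and genes of endothelium (11 of 13, adjusted p = 9.71e-04, or 0.411) and erythrocytes (6 of 6, median -2.12, adjusted p = 0.00684, or 0.453) fell. Schwann cell genes fell in 8 of 13 (adjusted p = 0.0146, or 0.579), without KO control replicate 3 at an adjusted p of 0.0642. Granulocyte and mast cell genes fell in 6 of 11 (adjusted p = 0.0459, or 0.579), a call that ended without any 1 of WT control replicate 2, KO control replicates 1 and 3 and KO denervated replicates 2 and 3 (up to 0.105).

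The responses of the genotypes overlapped widely. Of the genes called in each, 4863 were called in the same direction, 2309 higher and 2554 lower, against 675 and 727 expected by chance, and 13 in opposite directions. The comparisons share no array. Across all 15226 genes the log2 changes correlated with r = 0.880 and rho = 0.854, across genes, which are not independent replicates.

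**Figure D2:**
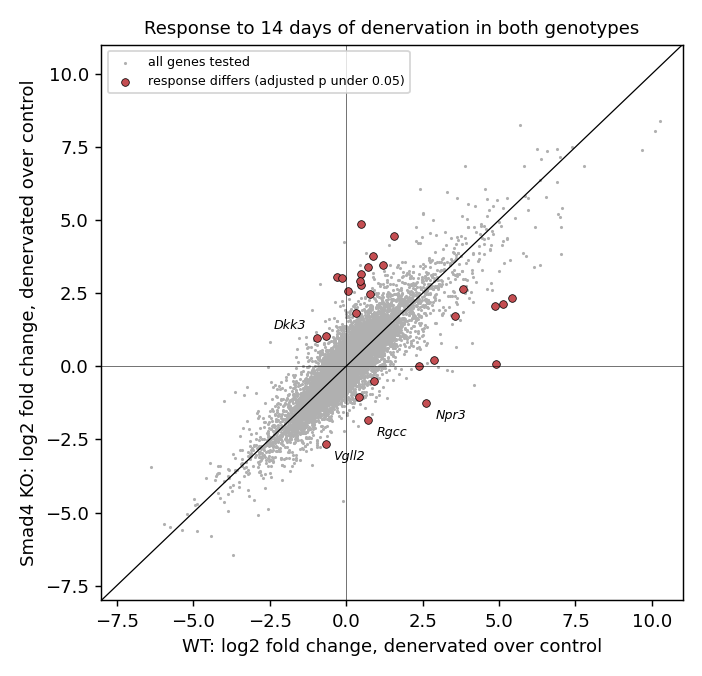
Log2 change after denervation of each of 15226 genes in WT (horizontal) and KO muscle (vertical); the diagonal marks equal change, and larger points mark the 28 genes whose responses differed in the interaction test. Most points lie along the diagonal (r = 0.880 across genes).

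The comparison of KO with WT control muscle asks what loss of Smad4 did to muscle with its nerve. Smad4 alone passed the test, lower by 2.75-fold (log2 -1.46 ± 0.15 SE, n = 3 against 3, limma adjusted p = 0.0185), on all 3 KO arrays against all 3 WT arrays and within slide 2 (-1.21) and slide 3 (-1.83). At an unadjusted p under 0.05 there were 616 genes. The call hung on single arrays. It ended without any 1 of WT control replicates 1 and 3, KO control replicates 1, 2 and 3, WT denervated replicate 3 and KO denervated replicate 3 (adjusted p up to 0.142) and with slide as a block (0.142), while the log2 change stayed near its size (-1.53 with the block). Without WT denervated replicate 2, KO denervated replicate 1 or KO denervated replicate 2, 2 genes passed. The count was 5 with quantile normalization, the array median or the series matrix, and 0 with no filter, the replicate block, the planned normexp correction or only the arrays of the 2 groups. The receptor, embryonic and ubiquitin ligase genes of the fixed panel did not pass: Chrna1 was at -0.23 ± 0.13, Myog at 0.23 ± 0.37, Fbxo30 at 0.06 ± 0.24, Mstn at -0.04 ± 0.18 and Id1 at -0.02 ± 0.39, each with an adjusted p of 1. Camera called 7 lists, in which no member other than Smad4 passed over all genes tested. They were the Smad family (median -0.08, 1 lower adjusted over the list alone, adjusted p = 0.00599, or adjusted p = 0.269 with an estimated correlation), fast-fibre genes (median 0.13, 0.00599, or 0.752), slow-fibre genes (0.20, 0.00631, or 0.752), extracellular matrix (0.27, 0.00492, or 0.915), oxidative phosphorylation (0.08, 0.0135, or 0.915), myogenic regulators (0.20, 0.0492, or 0.752) and erythrocyte genes (-0.66, 0.0108, or 0.752). The Smad family list holds Smad4, the knocked-out gene, so its call does not show a change of the other members. No test of that list without Smad4 is given here. Within slides 2 and 3 the medians had opposite signs for fast-fibre genes (0.28 and -0.02), oxidative phosphorylation (0.16 and -0.10) and myogenic regulators (0.22 and -0.07). With slide as a block the adjusted p of oxidative phosphorylation was 0.123. Quantile normalization left 3 of these lists called, with an adjusted p of 0.566 for fast-fibre genes, 0.0674 for slow-fibre genes and myogenic regulators, and 0.367 for oxidative phosphorylation. Without a filter it was 0.0873 for extracellular matrix, 0.0922 for fast-fibre genes, 0.324 for myogenic regulators and 0.51 for oxidative phosphorylation. Single arrays ended 6 of the 7 calls. Without KO control replicate 1 the adjusted p was 0.919 for extracellular matrix and 0.318 for myogenic regulators. Without WT control replicate 1 it was 0.203 for fast-fibre genes and 0.654 for oxidative phosphorylation. Without WT control replicate 3 it was 0.101 for slow-fibre genes, and without WT control replicate 2 0.182 for erythrocyte genes.

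The comparison of KO with WT denervated muscle asks how loss of Smad4 changed muscle that had lost its nerve. Some of the genes that BMP signals switch on, 5 of the 14 measured, were lower in the KO. Atoh8, a transcription factor, was lower by 5.22-fold (log2 -2.38 ± 0.33 SE, n = 3 against 3, adjusted p = 0.00436), the inhibitors of differentiation Id2 by 4.69-fold (-2.23 ± 0.32) and Id3 by 2.2-fold (-1.14 ± 0.19), and Smad6, an inhibitory Smad, by 2.22-fold (-1.15 ± 0.16). Id1 went the same way without passing (-1.26 ± 0.39, adjusted p = 0.139), and Nog was at -0.79 ± 0.50 (adjusted p = 0.474). The largest falls in the KO were those of Npr3, the clearance receptor of natriuretic peptides (-3.89 ± 0.26), Igfn1 (-2.93 ± 0.55), the metalloprotease Adamts8 (-2.68 ± 0.46), the cell cycle regulator Rgcc (-2.65 ± 0.21), the alpha-1B adrenergic receptor Adra1b (-2.59 ± 0.25), the amino acid transporter Slc7a8 (-2.42 ± 0.32), Kcnc1 (-2.39 ± 0.31) and Atoh8. The potassium channel gene Kcnf1 was at least 13.4-fold lower, Ankrd55 at least 9.71-fold and Wfdc2 at least 6.51-fold. Higher in the KO were the IGF-binding protein Igfbp2 (3.37 ± 0.58), the cytokine receptor Il20rb (3.35 ± 0.35), Aldh3a1 (3.25 ± 0.44), the cyclin-dependent kinase inhibitor Cdkn1c (3.06 ± 0.27), the stress hormone Fgf21 (2.87 ± 0.44), the cation channel Trpm2 (2.82 ± 0.45), the adenosine receptor Adora2b (2.68 ± 0.22) and the docking protein Efs (2.67 ± 0.34). For each gene called here the 3 KO arrays lay on one side of the 3 WT arrays, which the rule behind the largest changes requires. The calls of Igfn1 and Adamts8 ended without single arrays (adjusted p up to 0.0774 for Igfn1, without WT denervated replicates 2 or 3 or KO denervated replicate 2; up to 0.0553 for Adamts8, without WT denervated replicate 2 or KO denervated replicates 2 or 3), and those of Igfbp2 (0.0608) and Wfdc2 (0.0564) without KO denervated replicate 2.

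In all, 333 genes differed between KO and WT denervated muscle (limma, adjusted p under 0.05), 146 higher and 187 lower in the KO, 229 of them by at least 2-fold. The count was 219 without WT denervated replicate 1, 152 without WT denervated replicate 2, 154 without KO denervated replicate 2 and 194 without KO denervated replicate 3. It was 354 with slide as a block. The planned normexp correction called 25, 17 higher and 8 lower, no filter 203 and only the arrays of the 2 groups 126. Of the 333, 210 had the same sign in control muscle. The split into higher and lower genes moved with the scaling, to 181 and 183 under quantile normalization and 117 and 246 with the array median. Among them 220 were also called for denervation in WT, 121 with the same sign as that response and 99 with the opposite sign. Between control and denervated muscle the genotype effects correlated with r = 0.180 and rho = 0.0685, across genes, which are not independent replicates. In the fixed panel Musk was lower by 1.39 on the log2 scale in the KO (adjusted p = 0.0344), a call that ended without WT denervated replicates 1, 2 or 3 or KO denervated replicates 1 or 2 (up to 0.134) and with slide as a block (0.0729). The receptor subunit gene Chrnd was lower by 0.89 (adjusted p = 0.0187), a call that ended without WT denervated replicates 2 or 3 or KO denervated replicates 2 or 3 (up to 0.0789), with slide as a block (0.0633), with either normexp correction and with only the arrays of the 2 groups; its interaction did not pass (adjusted p = 0.451). Among panel genes that did not pass, Chrna1 was at -0.38 ± 0.13, Myog at -0.42 ± 0.37, Mstn at -0.69 ± 0.18 (adjusted p = 0.0783), Ncam1 at -1.50 ± 0.44 (adjusted p = 0.116), Fbxo30 at 0.37 ± 0.24, Fbxo32 at 0.16 ± 0.51, Trim63 at 0.45 ± 0.23 and Gdf5 at 0.29 ± 0.34.

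By list, camera called 13 in denervated KO against WT muscle. Of 14 BMP target genes 5 were lower and none higher over all genes tested, and 6 lower adjusted over the list alone (median -0.57; adjusted p = 3.61e-05, or adjusted p = 0.241 with an estimated correlation); within slides 1 and 4 the medians were -0.55 and -0.83. In the Smad family Smad4, Smad6 and Smad7 were lower (adjusted p = 0.00376, or 0.241 with an estimated correlation), Smad7 (-1.48) only until WT denervated replicates 1 or 2, KO denervated replicates 2 or 3, WT control replicate 3 or KO control replicates 2 or 3 were left out (adjusted p up to 0.122). The Smad family list holds the knocked-out gene itself, and Smad6 and Smad7 are also in the BMP target list, so these calls are not separate findings. TGF-beta target genes were not called (0 of 18 past the test over all genes, with a median of 0.06 and an adjusted p of 0.302). Embryonic and denervation-induced genes were lower (3 of 17, 7 adjusted over the list alone; median -0.55, adjusted p = 1.69e-04, or 0.246), with the potassium channel Kcnn3 at -1.78. Neuromuscular junction genes were lower (3 of 19; median -0.30, adjusted p = 0.0086, or 0.246), with an adjusted p of 0.0522 without WT denervated replicate 1. Metabolic lists were lower by small amounts with few members past the test. These were the citric acid cycle and fatty acid oxidation (3 of 37; median -0.38, adjusted p = 2.38e-08, or 0.241; Fabp3, a fatty acid carrier, at -1.33), oxidative phosphorylation (1 of 53; median -0.28, but -0.08 under quantile normalization; 1.19e-07, or 0.402) and glycolysis (1 lower and 1 higher of 20; median -0.27; 0.00685, or 0.33). Fast-fibre genes (0 of 15; median -0.37, but -0.07 under quantile normalization; 8.92e-04, or 0.356) and excitation-contraction genes (2 of 20; median -0.28; 0.00126, or 0.246) were lower too. Under quantile normalization the calls of fast-fibre genes (adjusted p = 0.495) and glycolysis (0.283) ended. Cell cycle genes were higher as a list (median 0.53, adjusted p = 0.00205, or 0.356), but the 2 members past the test were Cdkn1c, which restrains the cycle and was higher, and Mcm6, a part of the replicative helicase, which was lower (-1.30). Extracellular matrix genes were higher (1 of 32; median 0.33, adjusted p = 0.00205, or 0.595), a call lost without WT denervated replicate 2 or KO denervated replicate 1 (up to 0.383). Beside these groups, erythrocyte genes were lower in the KO with no member past the test over all genes and 6 of 6 adjusted over the list alone (median -1.27, adjusted p = 2.96e-04, or 0.246). Macrophage genes were higher with 0 of 17 past the test (median 0.32, adjusted p = 0.0107, or 0.641), but not without WT denervated replicate 2 or KO denervated replicate 1 (up to 0.139).

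**Figure D3:**
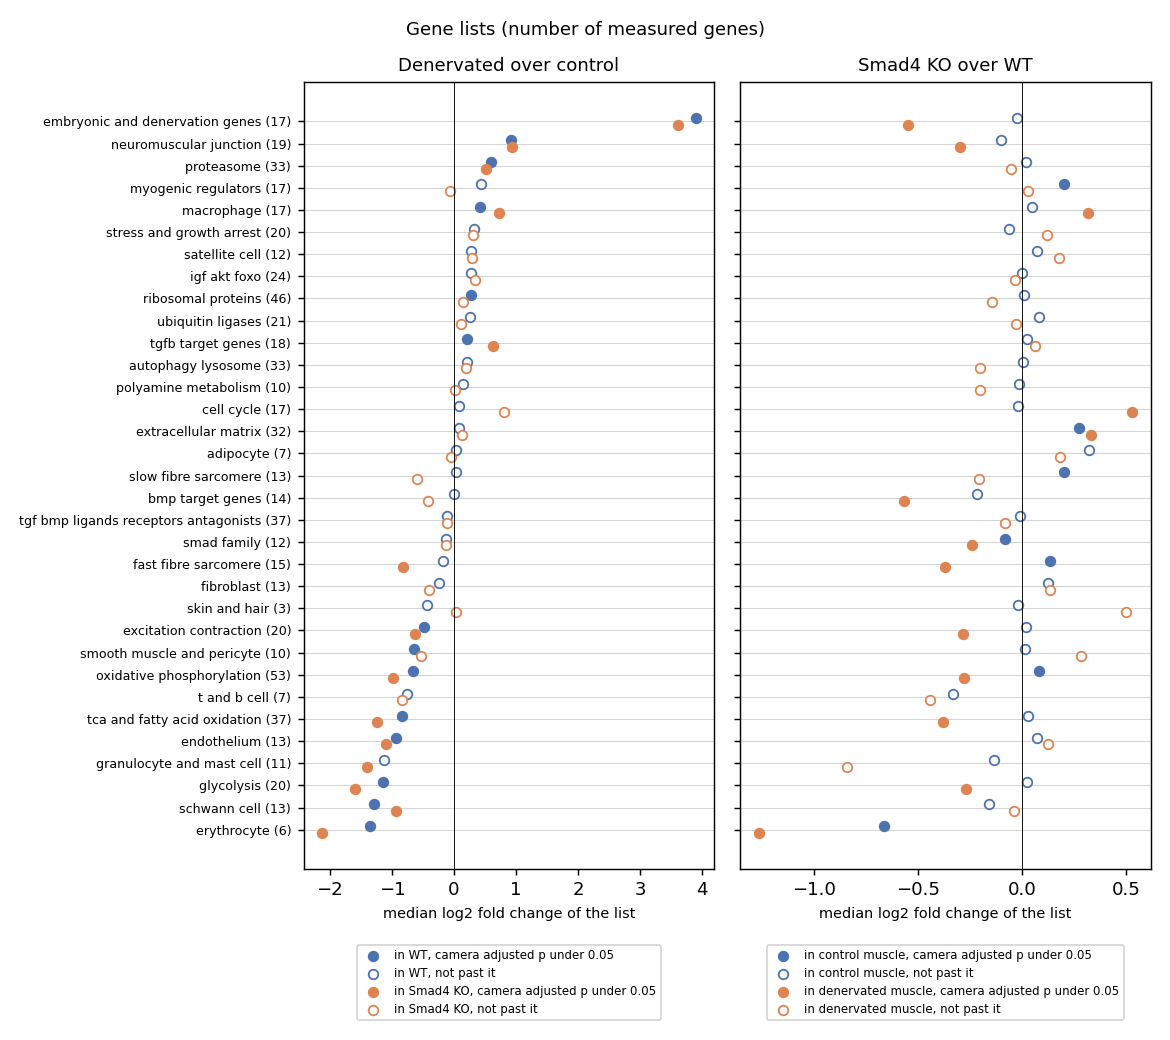
Median log2 change of the measured members of each gene list in each comparison; filled points mark lists called by camera (adjusted p under 0.05, preset correlation). With the correlation estimated from the data, no list was called in any comparison.

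The interaction asks whether denervation acted differently on KO and WT muscle. It called 28 genes, 15 with a higher and 13 with a lower response in the KO, out of 1437 at an unadjusted p under 0.05. The split moved to 25 and 17 under quantile normalization and turned to 10 and 14 with the array median. Npr3 rose after denervation in WT, to between 1.44 and 2.58 on the 3 arrays from between -0.51 and -0.38 in control muscle, and fell in the KO, to between -1.93 and -1.43 from between -0.58 and -0.35 (difference of responses -3.87 ± 0.37 SE, n = 3 per group, adjusted p = 0.00298). Rgcc (-2.55 ± 0.30, adjusted p = 0.0104), the tetraspanin Tspan9 (-1.46 ± 0.21) and Sh3bp4 (-1.41 ± 0.20) likewise rose in WT and fell in the KO. Vgll2, a cofactor of TEAD transcription factors in muscle, fell further in the KO (-1.99 ± 0.33), and the myosin light chain Myl12a rose less (-1.18 ± 0.18). Cdkn1c (2.68 ± 0.38, adjusted p = 0.0296), Adora2b (2.51 ± 0.32, adjusted p = 0.017) and the centromere histone chaperone Hjurp (2.45 ± 0.40) rose in the KO and did not pass the denervation test in WT, though Cdkn1c did with the WT pairs as a random block. The interferon-induced gene Ifitm7 rose more in the KO than in WT (1.72 ± 0.26). The secreted protein gene Dkk3 (1.95 ± 0.28) and stathmin, Stmn1 (1.70 ± 0.27), which binds tubulin, were lower after denervation in WT and higher in the KO. All 28 genes were also called between KO and WT denervated muscle, with the same sign. Among BMP targets, called between genotypes in denervated but not in control muscle, the interaction was -2.20 ± 0.47 for Atoh8 (adjusted p = 0.128), -1.88 for Id2 (0.166), -1.01 for Id3 (0.201) and -0.70 for Smad6 (0.357), so for none of these 4 genes was the genotype effect shown to depend on denervation. Musk did not pass either (-1.30, adjusted p = 0.322).

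For the other genes named in denervated muscle, none of them called in control muscle, the interaction passed for Adra1b and Ankrd55 and not for the rest. It was -3.00 for Adra1b (adjusted p = 0.0104). Among those that did not pass it was -0.76 for Slc7a8 (adjusted p = 0.642), -2.21 for Kcnc1 (0.0975), -2.47 for Adamts8 (0.201), -0.82 for Smad7 (0.608) and -1.19 for Mcm6 (0.0784). Among genes higher in the KO it was 2.96 for Igfbp2 (0.224), 2.75 for Il20rb (0.072) and 2.18 for Efs (0.134). For genes seen on no array of at least 1 group only the adjusted p is given: 0.0104 for Ankrd55, 0.877 for Igfn1, 0.158 for Aldh3a1, 0.15 for Fgf21, 0.188 for Trpm2, 0.0898 for Kcnf1 and 0.12 for Wfdc2.

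**Figure D4:**
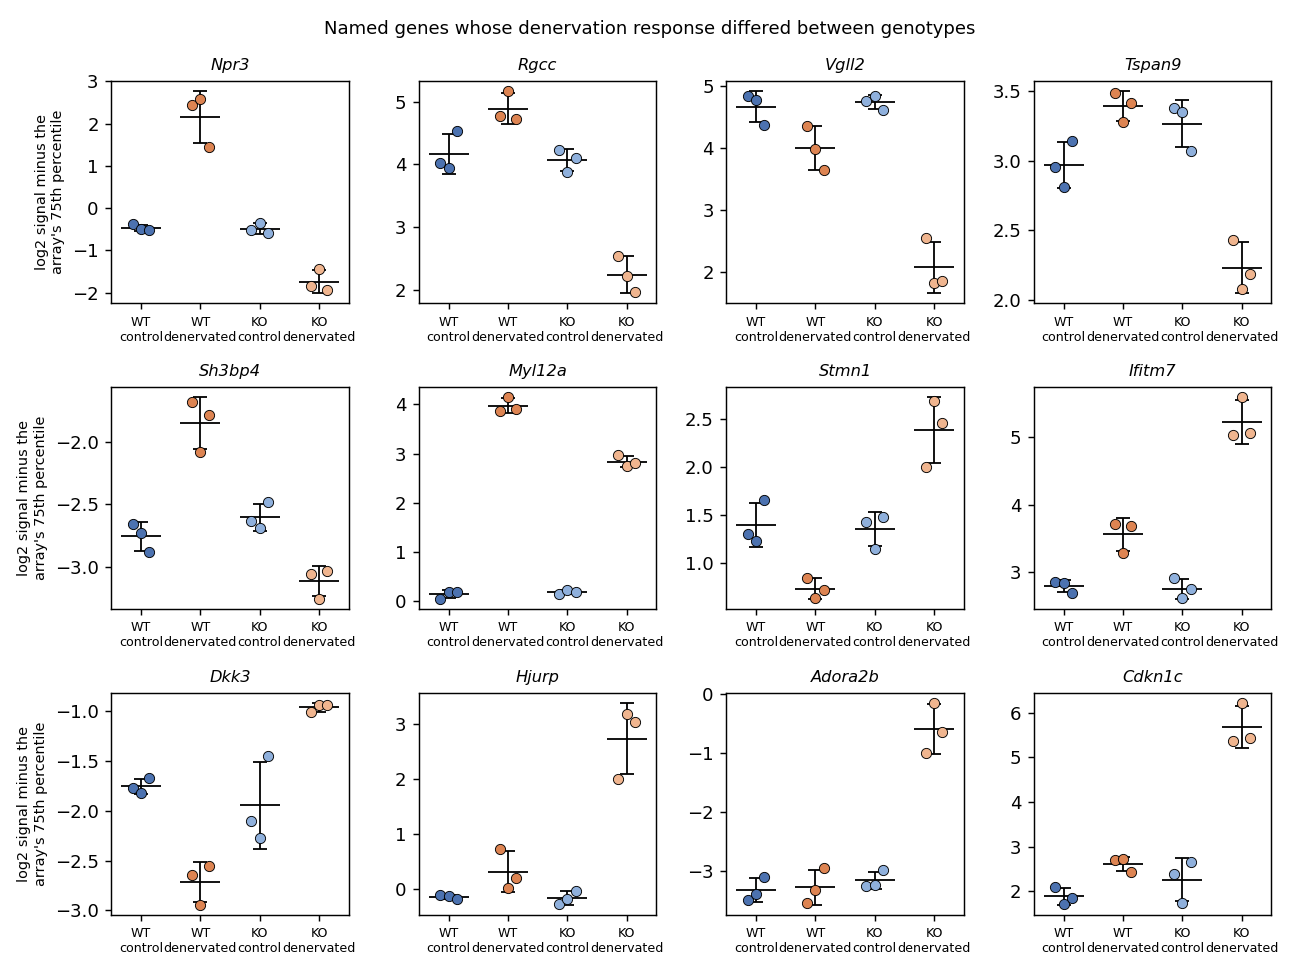
Signal of genes named for the interaction on each array (log2 signal minus the array's 75th percentile; points, arrays; horizontal bar, mean; error bar, SD of 3 arrays). The Npr3 values of the 3 KO denervated arrays lie between -1.93 and -1.43 and those of the WT denervated arrays between 1.44 and 2.58.

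The count of 28 was not stable. It was 6 without WT control replicate 1, 5 without WT control replicate 2, 13 without WT control replicate 3, 12 without WT denervated replicate 2, 17 without WT denervated replicate 3, 11 without KO control replicate 1, 5 without KO control replicate 2, 17 without KO control replicate 3, 10 without KO denervated replicate 2, 14 without KO denervated replicate 3 and 51 without KO denervated replicate 1. It was 5 with no filter, 12 with the filter on all 12 arrays and 0 with the planned normexp correction. With slide as a block it was 4, and the adjusted p of Npr3 became 0.0517 and that of Rgcc 0.0583, with differences of -3.86 and -2.50. With the replicate number within a genotype as a block, which pairs the KO arrays as well as the WT arrays, the count was 9. The adjusted p was then 0.0185 for Npr3 and 0.0528 for Rgcc. With only the WT pairs, as a random block, the count was 30. Npr3 and Rgcc alone of the 12 genes named kept their calls in every fit that left out 1 array. Adora2b lost its call without WT control replicate 2 or KO control replicate 2 (adjusted p up to 0.0694), Cdkn1c without 7 of the 12 arrays (up to 0.0927, without WT control replicate 2), and the other 8 without 8 to 11 of the 12. Camera called 9 lists, in which Cdkn1c was the only member past the test over all genes. The denervation response was more negative in the KO for oxidative phosphorylation (median difference -0.40, but -0.10 under quantile normalization; adjusted p = 1.3e-09, or adjusted p = 0.416 with an estimated correlation), the citric acid cycle and fatty acid oxidation (-0.38, 7.02e-08, or 0.38), glycolysis (-0.41, or -0.08 under quantile normalization; 0.0106, or 0.416), fast-fibre genes (-0.54, or -0.07; 5.49e-06, or 0.38), slow-fibre genes (-0.35, or -0.08; 0.00507, or 0.491), excitation-contraction genes (-0.36, 0.00327, or 0.38), embryonic and denervation-induced genes (-0.55, 0.00327, or 0.38) and BMP target genes (-0.42, 4 of 14 adjusted over the list alone, 0.00357, or 0.38). It was more positive for cell cycle genes (0.46, 0.0124, or 0.52), without a call once slide was a block (0.0559) or without WT denervated replicate 3, KO denervated replicate 1 or KO control replicate 2 (up to 0.112). Under quantile normalization 4 of the 9 lists were called. The call ended for glycolysis (adjusted p = 0.598), fast-fibre (0.444), slow-fibre (0.09), excitation-contraction (0.0836) and cell cycle genes (0.0586), and without a filter for glycolysis (0.0677). Without KO control replicate 3 the embryonic list had an adjusted p of 0.109, and without WT denervated replicate 1 the slow-fibre list one of 0.0643. Lists not called in the interaction but called for genotype in only one condition were neuromuscular junction (-0.24, 0.117), macrophage (0.22, 0.0551) and myogenic regulators (-0.18, 0.264). The erythrocyte list had a median difference of -0.69 (adjusted p = 0.103).

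The last comparison asks for the mean genotype effect over both conditions. A large effect in denervated muscle alone can pass it, and Smad4 was the only gene called in each condition by itself. Besides Smad4, lower genes in the KO were Slc7a8 (-2.04 ± 0.23, log2 and SE, 6 arrays against 6, adjusted p = 0.00275), the scaffold protein whirlin (Whrn, -1.63 ± 0.17), the potassium channel Kcnc4 (-1.54 ± 0.24), the collagen gene Col22a1 (-1.47 ± 0.21), Igsf1 (-1.19 ± 0.16), the arginine deiminase Padi2 (-1.15 ± 0.17) and the cyclase Dglucy (-1.09 ± 0.12). Higher were Lrrc17 (1.53 ± 0.27), the chemokine Cx3cl1 (1.52 ± 0.25), the matrix protein Cilp (1.44 ± 0.23), the Wnt antagonist Sfrp1 (1.13 ± 0.19), the transcription factor Sox4 (1.06 ± 0.18), the adhesion molecule Cadm1 (0.96 ± 0.20), the syndecan Sdc1 (0.88 ± 0.13) and Wdfy1 (1.20 ± 0.15, with probes from -0.23 to 2.03). For each of these, KO and WT arrays did not overlap in either condition, which the rule requires. The fit takes the 6 WT arrays as independent, although WT arrays with the same number correlated in pairs. With these pairs as a random block 125 genes passed, against 139 without it, and Cadm1 did not pass (adjusted p = 0.062). The calls of Smad4, Slc7a8, Whrn, Kcnc4, Col22a1, Igsf1, Padi2, Dglucy, Sdc1 and Wdfy1 were kept in every fit that left out 1 array. The others were not. The highest adjusted p was 0.052 for Cilp and 0.116 for Cadm1, both without KO denervated replicate 2, 0.0525 for Cx3cl1 without WT control replicate 2, 0.0561 for Sfrp1 and 0.0712 for Lrrc17 without WT denervated replicate 2, and 0.0597 for Sox4 without KO denervated replicate 2. Cilp (0.0618) and Cadm1 (0.0936) also lost theirs with slide as a block. In all 139 genes passed, 74 higher and 65 lower, of which 112 were also called in denervated muscle. The share of higher genes was 53.2%, as under quantile normalization. It was 46.9% with the array median, 49.6% with the series matrix and 66.7% with the planned normexp correction. The count was 83 without WT control replicate 1, 80 without WT control replicate 2, 88 without WT denervated replicate 2 and 81 without KO denervated replicate 2. It was 100 with slide as a block, 62 with no filter and 6 with the planned normexp correction. Of the BMP targets, 3 of 14 were lower (median -0.44, adjusted p = 1.7e-05, or adjusted p = 0.257 with an estimated correlation). Smad6 was called at -0.80 in every such fit, but Id2 at -1.29 (adjusted p up to 0.0721, without KO denervated replicate 2) and Atoh8 at -1.28 (up to 0.0812, without WT control replicate 2) not in all. Camera called 12 lists. Of the other 11, Smad family (-0.11, 3.87e-04, or 0.144), embryonic (-0.33, 3.87e-04, or 0.309), neuromuscular junction (-0.13, 0.00788, or 0.309), citric acid cycle and fatty acid oxidation (-0.19, 2.21e-05, or 0.309), oxidative phosphorylation (-0.10, 0.00589, or 0.636), excitation-contraction (-0.13, 0.00992, or 0.429), T and B cell (-0.32, 0.0436, or 0.495) and erythrocyte genes (-0.95, 3.41e-05, or 0.309) had negative medians. Extracellular matrix (0.26, 4.67e-05, or 0.539), cell cycle (0.20, 0.00992, or 0.539) and macrophage genes (0.17, 0.0436, or 0.636) had positive ones. The numbers given for each list are the median, the adjusted p and the adjusted p with an estimated correlation. The Smad family list again holds Smad4 itself. Quantile normalization ended the calls of oxidative phosphorylation (adjusted p = 0.232), excitation-contraction (0.117) and macrophage genes (0.0578), the last also without a filter (0.0641). Single arrays ended 5 of these calls: the adjusted p was 0.53 for macrophage, 0.112 for cell cycle and 0.0518 for excitation-contraction genes without KO control replicate 1, 0.139 for oxidative phosphorylation without WT denervated replicate 2 and 0.136 for T and B cell genes without WT control replicate 3.

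Across the 6 comparisons fry, limma's test of whether the members of a list move on balance one way, called 19, 25, 1, 10, 0 and 5 lists in the order given here, and its mixed form, which asks whether members change in either direction, called 30, 31, 1, 22, 13 and 16. Neither compares a list with other genes.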

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

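Of the tests in this part, the one on slides, those on the sex label, the splits that keep the WT pairs and the check of the denervation response with single WT arrays were chosen only after the result was seen, and the others before.

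By limma's interaction test the denervation response was called as different between KO and WT muscle for 12 genes named under the rule. The interaction was -3.87 for Npr3, -2.55 for Rgcc, -1.99 for Vgll2, -1.46 for Tspan9, -1.41 for Sh3bp4 and -1.18 for Myl12a. It was 2.68 for Cdkn1c, 2.51 for Adora2b, 2.45 for Hjurp, 1.95 for Dkk3, 1.72 for Ifitm7 and 1.70 for Stmn1. Of these genes Npr3 and Rgcc alone kept their calls in every fit that left out 1 array, and neither passed with slide as a block. With the planned normexp correction no gene passed. Camera also called 9 gene lists in the interaction, none of them with an estimated correlation. Their adjusted p was 0.00327 for embryonic and denervation-induced genes, 0.00357 for BMP target genes, 0.0106 for glycolysis, 1.3e-09 for oxidative phosphorylation and 7.02e-08 for the citric acid cycle and fatty acid oxidation. It was 5.49e-06 for fast-fibre genes, 0.00507 for slow-fibre genes, 0.00327 for excitation-contraction genes and 0.0124 for cell cycle genes. Under quantile normalization the calls of glycolysis, fast-fibre, slow-fibre, excitation-contraction and cell cycle genes ended.

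Chance could not be excluded for the number of genes in the interaction. Of 100 drawn splits of genotype within condition, 11 gave as many calls as the real 28, the real one included, and the highest of the others gave 109. All 10 other splits that gave as many kept the real genotypes of the denervated arrays and regrouped the control arrays only, and splits that parted the denervated genotypes gave at most 8. A split with several times the real count points to a structure of the samples, here the genotype difference among denervated arrays. The split that swaps the genotypes of the control arrays was left out of the draw, since it turns the interaction into the average and gives 139 genes. For the average over conditions only the real split, with 139 genes, gave as many among 100, and the highest other gave 109. That one was among the 12 others that kept the genotypes of the denervated arrays, and splits that parted these gave at most 8. Chance is argued against for a genotype difference among all arrays, though 1 of 100 is the smallest share that these splits can give. The splits do not tell a difference in both conditions from a difference in denervated muscle alone. For the comparisons of 3 against 3 arrays the splits are too few, with 1 of 10 as large in each. The real values were 5979 genes for denervation in WT, 7144 in KO, 1 for KO against WT in control and 333 in denervated muscle, and the highest other was 0 in each. WT arrays with the same number correlated in pairs, so other splits of those arrays also differ in how many pairs they part. Of the 28 splits of genotype within condition that part no WT pair, only the real one gave as many genes for the average (highest other 8) and for the interaction (0). None of the others kept the genotypes of the denervated arrays, so for the interaction they leave the answer above as it was. KO arrays of numbers 1 and 2 did not correlate above other numbers (r = 0.0899 and 0.0152), but those of number 3, which shared a slide, did (0.175). These splits were chosen for the WT pairs only, so even they are not strictly alike.

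The pattern weighed first is the genotype difference in denervated muscle, 333 genes. A difference in blood content between arrays is argued against for these genes as a set. With the mean of the erythrocyte list as a covariate the median ratio of the log2 changes after to before was 1.09, with quartiles of 0.914 and 1.25. The covariate is partly confounded with genotype. The list's median was between 1.02 and 2.25 on WT denervated arrays and between -0.19 and 1.06 on KO denervated arrays. Its slope therefore rests on the spread within groups, and the test does not decide for single genes. Calls fell to 57, of which 39 were among the 333. The median SE grew from 0.224 to 0.337 while residual degrees of freedom went from 8 to 7. The rest of the 57 were new calls, so values of single genes moved as well. The median size went from 1.26 (quartiles 0.920 and 1.90) to 1.34 (0.958 and 2.05). A difference between slides is argued against as well, since with slide as a block the ratio was 1.03 (quartiles 0.987 and 1.07), 354 genes were called and 253 of the 333 were among them.

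A larger shift along the denervation response in the KO is a biological alternative for the same 333 genes. If it were the cause, 80% or more of them were to have the sign of their denervation response in WT, and if not, 50% or fewer. The share was 53.2% (95% interval 47.6 to 58.6), against 53.7% of all genes, so the rule written beforehand did not decide. The WT denervated arrays enter both sides of that share, so it was repeated with the response taken from single WT denervated arrays and the genotype difference from the other 2: 53.8%, 52.3% and 53.8%, with upper bounds of at most 59.2%. This check, and the reading that upper bounds under 80% argue against such a shift as the whole cause, were chosen after the share was seen. The intervals treat genes as independent, which they are not. Other values go with a larger shift: on the first principal component the KO denervated arrays lay between 67.2 and 75.6 and the WT denervated arrays between 50.2 and 55.9, and 3071 of the 4863 shared changes were larger in the KO. The slope of the KO on the WT response over genes called in both was 1.02, which is near equal size. A larger shift as part of the difference stays open. With blood and slides argued against, and a larger shift argued against as the whole cause, an effect of Smad4 loss on denervated muscle stays open as a hypothesis found and tested on the same arrays, as does any other difference between the mice of the genotypes, which was not tested.

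The 139 genes called for the genotype effect averaged over conditions, 112 of them also called in denervated muscle, may also stem from alleles carried along with the Smad4 locus on chromosome 18. Of 138 called genes other than Smad4 with a known position, 1 lies there, against 2.47% of all genes (odds ratio 0.287, 95% interval 0.0072 to 1.64, Fisher's exact p = 0.268). The upper bound of 1.64 is below the ratio of 2 set beforehand as the least that this explanation would give, which argues against it for these genes as a set but not for any single gene.

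The other pattern weighed is the sex of the animals, which the labels give as adult male. An Xist probe was well above background on 12 of 12 arrays, and 7 probes of the Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d were so on 0 arrays. Failed Y-linked probes on samples of males are argued against, as they would leave Xist undetected. Samples of females are consistent with both values (12 and 0). At least 1 Xist probe was detected on every array of all 4 groups, though 2 of the 4 Xist probes were not, and a wrong label of this kind would apply to every group.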

How the results depend on the processing

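The normexp correction without spots of high local background and the random block of the WT pairs were chosen after the data were seen, and the other alternatives before. Where a value below moved, the cause was not tested unless stated.

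Smad4 averaged over conditions was lower in the KO under every alternative, from -1.49 to -1.29, and from -1.48 to -1.38 without single arrays. No scaling moved the median of all genes by more than 0.1. Over all values under alternatives other than leaving out an array, 14323 kept their call or lack of one (within slides, stayed within 1 SD), 476 lost their call, 234 gained one, 340 moved and 4 turned sign with a call on either side. Without single arrays the counts were 12708, 424, 119, 30 and 2.

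The planned normexp correction called 1909 genes for denervation in WT, 2721 in KO, 0 for KO in control muscle, 25 in denervated muscle, 0 for the interaction and 6 for the average, with 1576 shared between the denervation responses. The form without spots of high local background called 5033, 6640, 1, 431, 47 and 149. Both forms set spots marked as outliers missing, the planned one after the correction and this one before it. Spots of high local background were left out in this form only. Which of these differences raised the counts was not told.

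For KO against WT in control muscle, where limma called 1 gene and 616 had an unadjusted p under 0.05, quantile normalization, the array median and the series matrix gave 5, the mean of all probes and array weights 4, and trend with robust 3. The filter on all 12 arrays and slide as a random block gave 2. No filter, slide as a fixed block, the replicate block and only the arrays of the 2 groups gave 0. For KO against WT in denervated muscle, no filter gave 203 and only the 2 groups 126, the latter with fewer arrays behind the spread. The interaction count was 5 with no filter, 12 with the filter on all 12 arrays, 4 with slide as a fixed block and 9 with the replicate block. The average was 62 with no filter. Without a filter 27289 genes were adjusted for instead of 15226.

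Slide as a fixed block gave 4494 and 6637 genes for denervation in WT and KO, and 354 and 100 for KO in denervated muscle and on average. The replicate block gave 5720 for denervation in WT. The random block of the WT pairs gave 6342, 7154, 1, 343, 30 and 125 in the order below.

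Leaving out single arrays gave 4812 to 6125 genes for denervation in WT, 6101 to 7221 in KO and 4010 to 4556 shared. It gave 0 to 2 for KO in control muscle, 152 to 324 in denervated muscle, 5 to 51 for the interaction and 80 to 129 for the average. The arrays that move these by more than 1.5 times are named beside each count in the report. A group with an array left out keeps 2 arrays.

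Lists called by camera with an estimated correlation were 0 in all 6 comparisons. In the order WT, KO, control, denervated, interaction and average, camera called 14, 14, 7, 13, 9 and 12. Directional fry called 25 for denervation in KO, 1 for KO in control muscle, 0 for the interaction and 5 for the average. Its mixed form called 30 and 31 for denervation in WT and KO, and 1 and 22 for KO in control and denervated muscle. Quantile normalization gave 3 for KO in control muscle and 4 for the interaction. Without single arrays the numbers ranged from 11 to 15, 12 to 15, 6 to 9, 12 to 17, 8 to 14 and 8 to 13, the 14 without KO denervated replicate 2.

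Signs of single genes that did not pass turned in 80 of 539 values within slides, 105 of 7877 under other alternatives and 102 of 6563 without single arrays. Of genes that passed, none turned within slides or without single arrays, though many were chosen for arrays that do not overlap. With the planned normexp correction Kit (0.15) and Cd4 (0.13) turned positive for denervation in WT. With the series matrix Myf5, seen on no WT array, turned to -1.04 for denervation in WT. For KO in control muscle ribosomal proteins turned with slide as a block (adjusted p = 0.0443), and cell cycle (0.0439) and macrophage genes (0.00588) without KO control replicate 1. Without single arrays the adjusted p ranged from 0.0268 to 0.917 for cell cycle genes and from 2.98e-04 to 0.979 for the result macrophage, Smad4 KO in control muscle.

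Signal over background limits what falls can be measured: genes below the lowest signal well above background are not told from it, so single genes seen on no array of a group are mostly given as bounds, without a size, or by the smaller change of their probes where such a group is compared.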

Other observations

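KO control replicate 3 lay closer to denervated muscle than the other KO control arrays for several genes, chosen after their values were seen. Chrng was at -1.50 there and at -4.36 and -4.08 on KO control replicates 1 and 2. Krt18 was at 1.99 against -2.06 and -0.98, Runx1 at -2.97 against -3.54 and -5.38, and Aldh3a1 at -4.00 against -6.09 and -5.57. Chrng was well above background on 1 KO control array, Runx1 on 2 and Aldh3a1 on none, so their differences are not measured sizes. Chrna1 was at 2.46 against 2.31 and 2.32, and Gadd45a at 2.62 against 2.20 and 2.22. Over 60 genes that rose in WT the median difference of this array from the mean of the other 2 was 0.49, with 46 genes higher than that mean and 40 higher than both arrays. The same median was -0.39 and -0.23 for KO control replicates 1 and 2, and between -0.28 and 0.16 for the WT control arrays. On the first principal component KO control replicate 1 (-55.9) lay nearer to the denervated arrays than KO control replicate 3 (-57.1). No explanation was tested.

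On the first principal component the KO denervated arrays lay between 67.2 and 75.6 and the WT denervated arrays between 50.2 and 55.9.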
